A study of Mus musculus with 2 samples.

How the data were processed

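Total RNA from the cerebral cortex of NMRI mouse embryos at embryonic stage E14.5 was labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols. The series holds 1 wild type array and 1 Pax6-/- array. The design text speaks of 3 embryos per genotype, and the sources used here do not say whether their RNA was pooled on each array. MAS5, the Affymetrix signal algorithm, is named in the submitters' processing notes; its version, the scaling target and the detection calls are not given in the sources used here.

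The deposited values are intensities on a linear scale, 1 MAS5 signal per probe set and array. The 2% trimmed mean was 500.2 on both arrays, while the median was 237.3 on the wild type array and 283.7 on the mutant array, as 1 scaling factor per array would give, and the distributions of the authors' signal intensities still differed. No value was below 1.0. Because only the processed signals were used, the arrays' own background and probe-level data were not examined.

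The table holds 12488 probe sets, of which 66 are Affymetrix controls. GEO's platform annotation gave 1 gene symbol for 10855 probe sets, several for 396 and none for 1237. Of the 10855, 10839 matched the mouse gene table (GRCm38.p6) by gene ID, and 0 symbols needed an update. No gene was named from a probe set with several symbols. A gene was represented by its probe set with the highest mean signal, which left 8251 genes.

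The choices that follow, the gene lists and the alternatives were fixed before the data were examined. A pseudocount of 81.5, the 25th percentile of all signals, was added before taking log2, and the mutant minus wild type difference was centred on its median over the probe sets passing the filter, which removed a shift of 0.05. The signal filter kept probe sets whose mean log2 value lay at or above the 40th percentile, a signal of about 166, and left 5585 genes. All log2 ratios and folds are on this scale, mutant over wild type, and so understate the difference of dim genes. With 1 array per genotype no test between genotypes is possible, no p-value is given, and genes are reported by size, with a 2-fold difference as the threshold.

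A technical spread was taken from the 893 genes with at least 2 probe sets above the filter: the SD of the difference in log2 ratio between the 2 brightest, divided by the square root of 2. It holds nothing of the variation between embryos. The number of arrays limits the precision of every value.

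For each of 26 gene lists, the median log2 ratio of the members above the filter was set among the medians of 10000 random lists of the same size, matched in 20 bins of mean signal, and given as a percentile. This describes these arrays and is not a test of the genotype. The lists covered radial glia, intermediate progenitors, deep-layer and upper-layer cortical neurons, Cajal-Retzius cells, the subpallial and GABAergic lineage, the pallial-subpallial boundary, arealization, adhesion and guidance, Wnt and Notch signalling, the cell cycle, neuronal differentiation, glia, genes linked to Pax6 by general knowledge, and ribosomal, glycolysis and immediate early genes. Further lists marked erythroid, vascular, meningeal, microglial, choroid plexus, diencephalic and eye or epithelial cells and the sex of the embryos. Older names were matched through the gene table, which placed Eomes in the Cajal-Retzius list under its alias.

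The genes named are Pax6; the 12 highest and 12 lowest log2 ratios of at least 2-fold whose other probe sets above the filter had the same sign; list members at least 2-fold apart; the 4 members of each list with the largest difference; and the Gapdh and beta-actin control probe sets. This rule gave 116 genes and left 24 genes past 2-fold out of the ranking, because another probe set had the opposite sign. A few others are marked as chosen after their values were seen.

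Alternatives were no centring, quantile and loess scaling (fraction 0.4, 3 iterations), no pseudocount (values floored at the 1st percentile) or the 50th percentile, no filter or the 60th percentile, the mean of a gene's probe sets, probe sets without a suffix for shared probes, thresholds of 1.5-fold and 3-fold, and matching in 5 bins. The steps were tested on simulated arrays of 5585 genes for this comparison. Of genes simulated with a log2 change of 2, 89.9% were recovered past 2-fold, against 35.7% for a log2 change of 1, and 2.1% of unchanged genes passed. These rates hold only for the noise that was simulated. The technical spread of the deposited arrays was 0.70 at signals below 292, where a larger share of unchanged genes would pass. The 2.1% is therefore no estimate of how many 2-fold genes on these arrays arise from technical spread. Of 100 random lists, 5 fell outside the central 95% of their random lists, and all 20 lists shifted by 0.6 lay above it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.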

Results

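Gene expression was compared between wild type and Pax6-/- cerebral cortex at embryonic stage E14.5, a stage at which the transcription factor Pax6 is strongly expressed in the cortical ventricular zone, to find genes that depend on it. Each genotype was represented by 1 array of MAS5 signals, with no replicate array, so no difference below has a replicate check and no p-value is given. The median signal was 237.3 on the wild type array and 283.7 on the mutant array. Signals ranged from 1.0 to 97796 on the wild type array and from 1.0 to 67512 on the mutant array. The log2 signals of both arrays correlated with r = 0.909 across 12488 probe sets, which are not independent replicates.

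Pax6 itself, measured by 1 probe set, had a signal of 1169 in wild type and 447 in the mutant, a log2 ratio of −1.29 against a technical spread of 0.37 at that signal level. The labels do not name the allele, and whether this probe set lies in the altered part of the gene is not known here; a probe set outside that part would be no check of the labels. Across 5585 genes above the signal filter, 282 were at least 2-fold higher and 305 at least 2-fold lower in the mutant, together 10.5% of the genes. Of those, 64.6% lay in the 3 dimmest of 10 equal groups of genes by signal. After loess scaling the split moved to 210 higher and 364 lower, or 36.6% higher against 48.0%. The spread between probe sets of the same gene was 0.56 on the log2 scale, against an SD of 0.62 over all genes, and it narrowed from 0.70 at signals below 292 to 0.56 below 535 and 0.37 above that. Of the 52 genes whose brightest of 2 or more probe sets was 2-fold apart, 29 had a second probe set of the same sign and 8 had one that was also 2-fold apart in the same direction; with second probe sets reassigned among genes of similar signal, the means were 24.2 and 4.2, and 1095 and 470 of 10000 reassignments reached these counts. Across the 893 genes with 2 probe sets above the filter, which are not independent replicates, the log2 ratios of both probe sets correlated with r = 0.10.

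**Figure D1:**
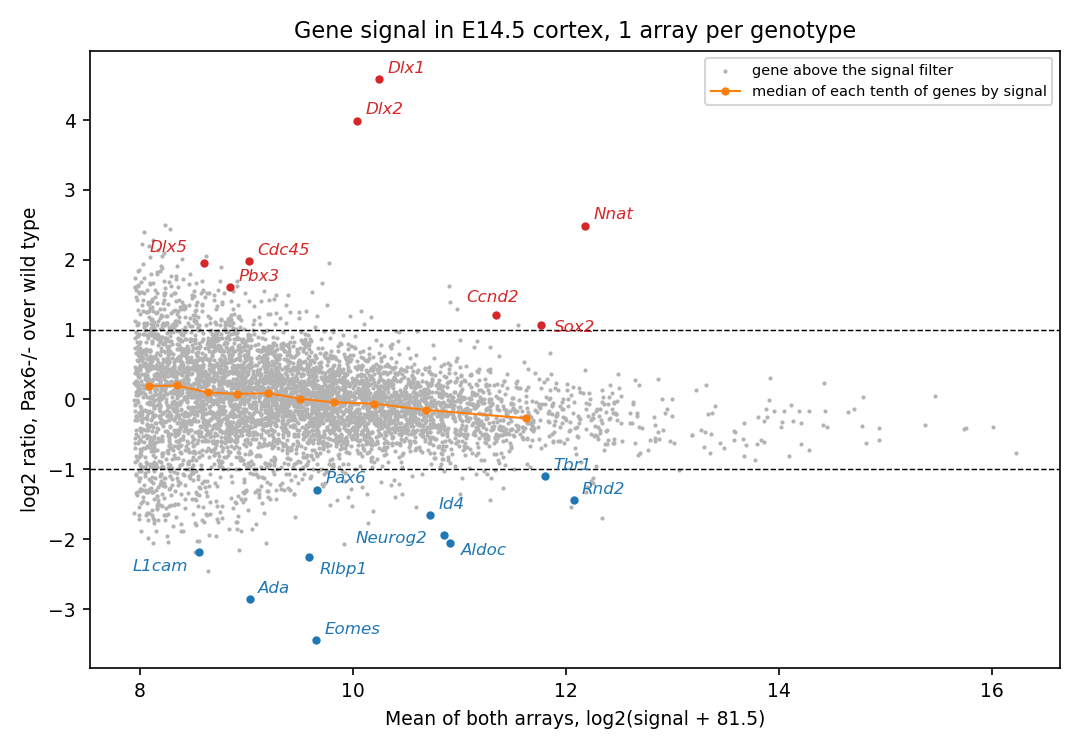
Log2 ratio of Pax6-/- over wild type (y axis) against the mean log2 signal plus pseudocount of both arrays (x axis); each grey point is 1 of 5585 genes, dashed lines mark 2-fold, red and blue points are named genes that were higher or lower, and the orange line joins the medians of 10 equal groups of genes by signal. Dlx1 at 4.59, Dlx2 at 3.99 and Nnat at 2.49 stand above, and Eomes at −3.44 below, the cloud of genes of similar signal, whose median runs from 0.19 in the dimmest group to −0.27 in the brightest.

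Most of the measured genes of the cortical neurogenic lineage were lower in the mutant. Eomes (Tbr2), the transcription factor that marks intermediate progenitors, was 10.87-fold lower, with a signal of 2535 in wild type and 167 in the mutant, and its second probe set had a log2 ratio of −1.39. Over the alternatives its log2 ratio ran from −3.97 to −2.41. Neurog2, a proneural factor of the dorsal telencephalon, was 3.85-fold lower, from 3490 to 877. Rnd2, a small GTPase of migrating cortical neurons, was 2.72-fold lower, Neurod1 2.70-fold, the somatostatin receptor gene Sstr2 2.62-fold and the Notch ligand gene Dll1 2.32-fold. All 3 Sstr2 probe sets had the same sign, with log2 ratios of −1.39, −0.85 and −0.62. Of the 16 members of the list of intermediate progenitors and proneural genes above the filter, 12 were lower and 4 higher, 6 of them at least 2-fold lower and 0 at least 2-fold higher. The list median was −0.40, the 1.78th percentile of matched random lists. With loess and quantile scaling the median was −0.24, at the 2.66th and 2.58th percentiles, just inside the central 95%.

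Markers of cortical glutamatergic neurons lay on the same side. Among deep-layer and subplate genes, 11 of 12 were lower and 1 was higher, with a median of −0.43 at the 1.99th percentile. Tbr1, which specifies early-born deep-layer neurons, was 2.15-fold lower, from 5088 to 2405. Its log2 ratio ran from −1.15 to −0.86 over the alternatives, past 2-fold in 7 of 9. Neurod2 at −0.98, Sox5 at −0.97 and Neurod6 at −0.94 followed just below the 2-fold mark. Of 8 upper-layer markers, 5 were lower and 3 higher, with a median of −0.49 at the 1.53th percentile. Plxnd1, a semaphorin receptor, had signals of 347 and 61.7, and Limch1 was 2.35-fold lower, although the second Limch1 probe set had a log2 ratio of 0.01. Cux1 was at −0.77 and Inhba at 0.86. The percentile of the upper-layer list ranged up to 6.75 over the alternatives. Of 20 genes linked to Pax6 by general knowledge, 17 were lower and 5 of those were at least 2-fold lower, namely Eomes, Neurog2, Neurod1, Dll1 and Tbr1. The median of that list was −0.21, at the 10.21th percentile. Pan-neuronal genes had a median of −0.25 at the 18.41th percentile, with 15 of 21 lower. Map2 was just short of 2-fold at −1.0, Gap43 at −0.93 and Nsg2 at −0.77, while Scg3 was at 0.74. The other Scg3 probe set, below the filter, was at −1.57. After loess scaling the pan-neuronal median was −0.02.

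Genes of the subpallium, the ventral telencephalon that produces GABAergic neurons, were higher in the mutant cortex. Dlx1 and Dlx2, neighbouring homeobox genes of the subpallial program, showed the largest ratios of all genes above the filter. The Dlx1 signal was 162 in wild type and 5982 in the mutant, a 24.13-fold difference, and that of Dlx2 was 179 and 4180, a 15.88-fold difference. These folds rest in part on the pseudocount, because the wild type signals lay near the filter level: over the alternatives the log2 ratio ran from 3.86 to 5.16 for Dlx1 and from 3.31 to 4.50 for Dlx2. Dlx5 was 3.89-fold higher, from 113 to 699, with a log2 ratio between 1.33 and 2.58 over the alternatives. Pbx3, a homeobox gene of the striatal lineage, was 3.04-fold higher, and its 3 probe sets had the same sign. Of the 10 list members above the filter, 8 were higher and 2 lower, 4 of them at least 2-fold higher. Penk, chosen after its values were seen, counts as higher at 0.94, although its other probe set above the filter was at −1.48. The list median was 0.95, and 1 of 10000 matched random lists was as high. The filter uses the mean of both arrays. Members with a wild type signal below about 166, such as Dlx1 and Dlx5, therefore passed it only through a higher mutant signal. This selection favours a high median, and matching random lists on mean signal does not remove it. Among members chosen after their values were seen, Gad1, which makes GABA, was at 0.97 and the vesicular GABA transporter gene Slc32a1 at 0.88, while the interneuron genes Lhx6 and Npy were at −0.68 and −0.48. A further 16 members on the array lay below the filter; with no filter the list median was 0.18, at the 86.70th percentile. Meningeal and mesenchymal genes, whose cells the dissection could hold, had a median of 0.30 on the same arrays.

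**Figure D2:**
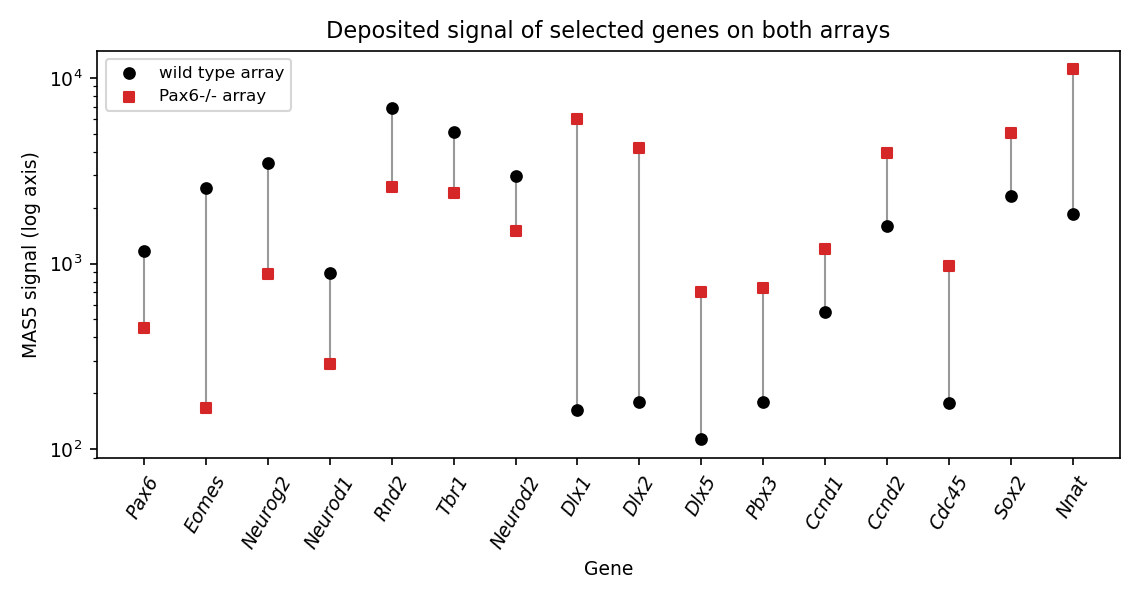
Deposited MAS5 signal (y axis, log scale) of 16 genes (x axis) on the wild type array (black circles) and the Pax6-/- array (red squares), 1 array each, with no error bars because there were no replicates. Pax6 and the 6 neurogenic genes to its right were lower in the mutant, whereas the Dlx genes, Pbx3, the cyclin genes, Cdc45, Sox2 and Nnat were higher.

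The list for the boundary between pallium and subpallium had 5 members above the filter and a median of −1.65, below all 10000 random lists. Its 3 members past 2-fold were Rlbp1, a retinaldehyde-binding protein gene, at 4.79-fold lower, Neurog2, which is shared with the neurogenic list, and Fgf15, a fibroblast growth factor gene, at 3.13-fold lower (log2 ratio −2.33 to −1.04 over the alternatives). Ptprk was at 0.58. The remaining member, Sfrp2, chosen after its values were seen, was almost equal on both arrays, at 668.5 and 670.6 (log2 ratio −0.04). The low median thus rests on 3 of 5 members. With no filter the median was −0.29, at the 17.69th percentile. Of 6 genes in the list of Cajal-Retzius and preplate cells, 5 were higher and Eomes was lower, with a median of 0.14 but a mean of −0.27. Zic1 was 2.34-fold higher, and Ebf2 was at 0.27, while the Ebf3 probe sets disagreed in sign, at 0.24 and −0.45. In the arealization list the median was −0.03, at the 42.59th percentile, and 0.08 after loess scaling. Nr2f2, a nuclear receptor gene of caudal and ventral territories, was 2.32-fold higher, whereas its relative Nr2f1 was at −0.70. Fgf17 was at 0.73.

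Cell cycle genes were higher in the mutant as a group, by small amounts. Of 41 members above the filter, 34 were higher and 7 lower, and the median of 0.26 exceeded all 10000 matched random lists, whose own median was −0.12. Cdc45, a replication factor gene, was 3.94-fold higher and the G1 cyclin gene Ccnd2 2.32-fold higher, from 1597 to 3939. Ccnd1 was at 0.97, although its second probe set above the filter was at only 0.24, and Ccne1 was at −0.92. Over the alternatives the list median ranged from 0.21 to 0.37. The meningeal list, at 0.30, lay on the same side. Radial glia and progenitor genes did not share this position: 15 of 19 were lower, with a median of −0.21 at the 23.06th percentile. Aldoc was 4.13-fold lower, Id4 3.17-fold lower and Ptprz1 at −0.87, while Sox2, a progenitor transcription factor gene, was 2.08-fold higher, from 2304 to 5042. The Notch list had a median of −0.05 at the 51.74th percentile (0.03 after quantile scaling), with Dll1 as its only member past 2-fold, Numb at 0.71, Lfng at −0.61 and Notch3 at −0.59. The Wnt list had a median of −0.20 at the 16.25th percentile. Within it the feedback target Axin2 and the modulator Dkk3 were higher, with signals of 129 and 532 for Axin2 and of 60.8 and 389 for Dkk3, and Fzd9 and Fzd2 were at −0.83 and −0.77.

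Adhesion and axon guidance genes were lower. Of 23 members, 17 were lower and 6 higher, and the median of −0.47 lay at the 0.05th percentile, between 0.00 and 0.38 over the alternatives. L1cam, an adhesion molecule of growing axons, was 4.54-fold lower, from 710 to 98, with a log2 ratio between −2.90 and −1.48 over the alternatives. The semaphorin receptor gene Nrp1 was 2.90-fold lower, the ephrin gene Efna2 2.45-fold, the netrin receptor gene Dcc 2.36-fold and Nrcam 2.0-fold. The other Nrp1 probe set, below the filter, was at 0.08. Cdh6 was 2.08-fold higher, from a wild type signal of 140. Cdh4 (R-cadherin), chosen after its values were seen, was at −0.96.

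**Figure D3:**
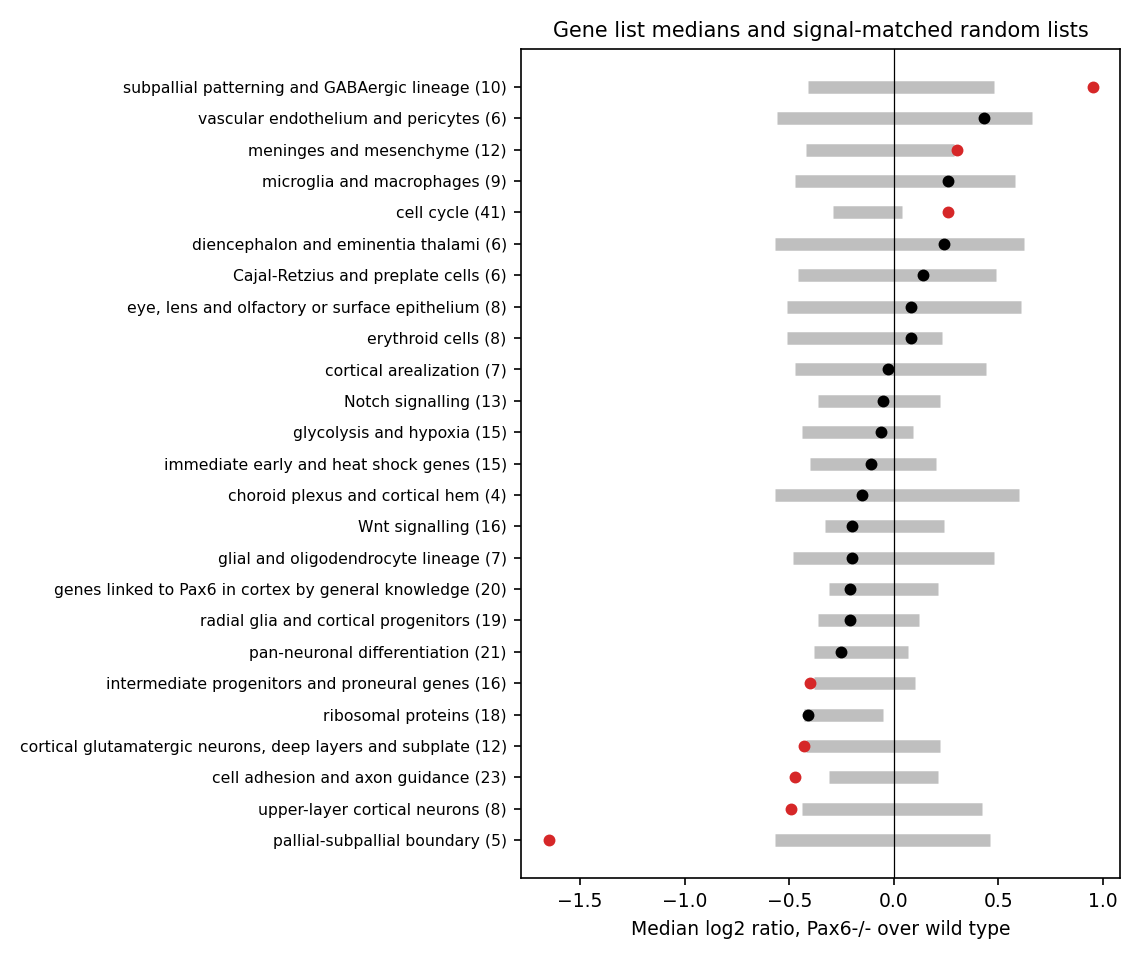
Median log2 ratio of Pax6-/- over wild type (x axis) for 25 gene lists (y axis, number of members above the filter in brackets); grey bars span the central 95% of 10000 random lists matched on signal, and points are red outside that range and black inside. The subpallial list at 0.95 and the cell cycle list at 0.26 lie to the right of their bars, and the pallial-subpallial boundary list at −1.65 and the adhesion list at −0.47 to the left.

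By size alone, the largest ratios outside these lists were mixed in strength. Nnat (neuronatin), an imprinted gene expressed in developing brain, was 5.61-fold higher, from 1852 to 11119. The other 9 of the 12 highest ratios came from wild type signals between 31.6 and 61.6, below the 25th percentile of that array, 71.3, and below the pseudocount. These were Trap1a, Snx21, Trh, Mrpl55, Zfyve16, Ccdc130, Acp5, Tcl1 and Padi4, each measured by 1 probe set, and the size and order of their ratios rest on the pseudocount: the log2 ratio of Trap1a ran from 1.55 to 3.85 over the alternatives and that of Snx21 from 1.53 to 3.66. Among the 12 lowest, Ada, which encodes adenosine deaminase, was 7.27-fold lower and Pde1b, a phosphodiesterase gene, 4.20-fold lower. Snd1 was 5.48-fold lower, Myh14 4.54-fold, Krt81 4.44-fold and Hsbp1 4.14-fold. The log2 ratio ran from −3.55 to −2.10 for Ada, from −3.24 to −1.68 for Snd1, from −2.93 to −1.46 for Myh14 and from −2.65 to −1.57 for Krt81 over the alternatives. Npas1 and Tbp were lower too, with signals of 482 and 57.8 and of 534 and 72.6, the lower ones below the pseudocount. The remaining probe sets of Ada and Krt81 were below the filter, and none showed the difference. They were at −0.02 and 0.20 for Ada and at 0.05, 0.76 and 1.23 for Krt81, so each fold rests on 1 probe set.

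Markers of other cells that the dissection could hold were measured beside these groups. Meningeal and mesenchymal genes had a median of 0.30 at the 97.75th percentile, with 9 of 12 higher. Twist2 was 2.87-fold higher, Igf2 2.05-fold lower, Foxc2 at 0.90 and the 3 Fbln1 probe sets above the filter at −0.40, 0.19 and 0.38. This list stayed outside the central 95% in 4 of 10 alternatives. Erythroid genes had a median of 0.08 at the 87.75th percentile; Hbb-y was at −0.63, Klf1 at 0.56, Slc4a1 at 0.50 and Tfrc at 0.22. The vascular list had a median of 0.43 at the 87.49th percentile, with the tight junction gene Cldn5 2.09-fold higher and Eng at −0.96. Microglial genes had a median of 0.26 at the 73.38th percentile, and of 1.20 at the 99.96th with the 60th-percentile filter. There the Csf1r probe sets were at 1.54 and 0.34 and Cx3cr1 at 0.90, Laptm5 was 2.57-fold lower, and the C1qb probe sets disagreed, at 1.14 and −0.93. Choroid plexus and hem genes had a median of −0.15 at the 24.52th percentile, with Foxj1 at −0.54 and Ttr at −0.16. Diencephalic genes had a median of 0.24 at the 73.42th percentile, with Lhx9 2.17-fold higher, from a wild type signal of 85.1, near the pseudocount. The log2 ratio of Lhx9 ran from 0.64 to 1.16 over the alternatives, past 2-fold in 4 of the 7 that measured it. Eye and epithelial genes had a median of 0.08 at the 49.23th percentile (−0.01 after loess scaling), with Rax at signals of 387 and 96.4. The glial list had a median of −0.20 at the 20.73th percentile, with the proteoglycan gene Bcan 3.36-fold lower. Of the sex-linked genes, Eif2s3y had signals of 430 and 519, and Xist, at 12.9 and 40.9, was below the filter on both arrays, so no median was formed.

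Stress, metabolic and ribosomal gene lists lay inside the central 95% of random lists in the main setting. Immediate early and heat shock genes had a median of −0.11 at the 50.45th percentile (0.01 after loess scaling), although Egr2 was higher, with signals of 68.3 and 465, Egr1 was higher, with a log2 ratio between 0.86 and 1.98 over the alternatives, and Junb was 2.22-fold lower; the Atf3 probe sets above the filter gave −1.75 and 0.16. Glycolysis and hypoxia genes had a median of −0.06 at the 81.92th percentile, with Ndrg1 2.30-fold and Ddit4 2.05-fold lower. The log2 ratio of Ddit4 ran from −1.09 to −0.88 over the alternatives, past 2-fold in 4 of 9. Ribosomal protein genes had a median of −0.41, with 15 of 18 lower, but their matched random lists had a median of −0.24 and the percentile was 3.87. Rpl22 was 2.64-fold lower and Rpl8 at −0.86. After loess scaling the ribosomal median was −0.09, and without probe sets for shared probes it was −0.58, at the 0.21th percentile. Against random lists matched in 5 bins of signal the ribosomal list lay at the 1.85th percentile, also outside the central 95%. Control probe sets for beta-actin had log2 ratios of −0.67 at the 3′ end, −0.84 in the middle and −0.97 at the 5′ end. Those for Gapdh were −0.06, −0.32 and −0.34, and turned to 0.34, 0.09 and 0.07 after loess scaling. Of 25 lists with a median, 8 lay outside the central 95% of random lists, where 1.25 would be expected for unrelated lists, and some lists share members.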

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

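Pax6 kept its direction and stayed within 1 technical spread of its log2 ratio under all 9 alternatives. The numbers of genes past 2-fold depended on the pseudocount, the filter and the threshold: 447 were higher without a pseudocount, 90 higher and 128 lower with the 50th-percentile pseudocount, 498 higher and 526 lower with no signal filter, and 97 higher and 114 lower with the 60th-percentile filter. At 1.5-fold the counts were 785 and 843, and at 3-fold 58 and 68. Of 223 recomputed list medians, 202 moved by less than 1 SD of their random lists. Under quantile and loess scaling, respectively, the medians were −0.24 and −0.24 for intermediate progenitors, 0.37 and 0.36 for the cell cycle, −0.02 and −0.02 for pan-neuronal genes and −0.12 and −0.09 for ribosomal proteins. These medians all rose. Loess scaling subtracts the trend by which bright genes were lower on the mutant array. In the main setting the matched random lists already had medians below 0, at −0.13, −0.12, −0.15 and −0.24 in that order. The subpallial median was 1.20 without a pseudocount, 0.67 with the larger one, 0.18 with no filter, which admits its dim members, and 2.86 with the 60th-percentile filter; the boundary median was −2.04, −1.04, −0.29 and −0.93 in that order. Vascular and diencephalic genes had too few members for a median under the 60th-percentile filter. That filter, which leaves fewer members, also gave −0.40 for arealization, 1.20 for microglia, at the 99.96th percentile against 73.38, and −0.35 for glycolysis and hypoxia. Without probe sets for shared probes, the medians were −0.37 for pan-neuronal genes and −0.58 for ribosomal proteins, and C1qb turned to −0.93, because its other probe set was used. Of 64 named genes past 2-fold besides Pax6, 39 were past it in the same direction under each alternative that measured them, and C1qb alone changed sign; the fold of 31 of the 64 moved by over 1.5 times under at least 1 alternative. The adhesion, deep-layer and cell cycle lists stayed outside the central 95% of random lists in all 10 alternatives, and the subpallial and boundary lists in all but the one with no filter. No paired analysis was possible because each genotype has 1 array, which also rules out leaving out a replicate. The number of arrays and the low signal of most 2-fold genes limit what can be read from single genes.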

Other observations

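The eminence, radial glia, spike-in and RNA-end tests and the reassignment of probe sets were chosen after the values they bear on had been seen; the loess scaling of the cell cycle list had been chosen beforehand and was read as a test of the trend after its value was seen, and the chromosome test was written down first. The criteria for the radial glia and spike-in tests were rewritten after their values were seen, and this is what left both open: under the earlier criteria the radial glia explanation was excluded and compression was borne out. Among genes with 2 probe sets above the filter, 8 were at least 2-fold apart in the same direction in both of their brightest ones, against a mean of 4.2 when second probe sets were reassigned among genes of similar signal; 470 of 10000 reassignments gave as many. The log2 ratios of both probe sets correlated with r = 0.10 across genes, or 0.26 at the highest signals, so some of the 8 are expected by chance. These genes were named after their values were seen. Eomes had log2 ratios of −3.44 and −1.39, the stress-responsive gene Ndrg1 −1.20 and −1.11, Mpdu1 −2.03 and −1.28, and Gpaa1, a subunit gene of the GPI-anchor transamidase, −1.24 and −1.34. On the higher side stood the homeobox gene Pbx3 at 1.61 and 1.59, the actin-capping gene Capg at 1.70 and 1.42, the hair keratin gene Krt35 at 1.08 and 1.58, and Klra7 at 1.55 and 1.21. Of the 841 probe sets above the filter without a single gene symbol, 62 were at least 2-fold higher and 28 at least 2-fold lower.

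Dlx1, Dlx2 and Dlx5 were higher on the mutant array. Tissue of the ganglionic eminences, where Dlx genes are normally active, in the mutant dissection is a candidate explanation beside ectopic expression in the cortex. The 6 lateral eminence and striatal markers above the filter had a median of 0.72, 4 of them higher (Gad1 0.97, Penk 0.94 though −1.48 in its other probe set, Ikzf1 0.94, Tac1 0.49) and 2 lower (Foxp1 −0.53, Drd2 −0.70), and all 14 on the array had a median of 0.14, from −1.23 for Meis2 to 1.13 for Six3, with Isl1 at 0.23, Gad2 at 0.10 and Dlx6 at 0.03; 17 of the 24 listed genes were also in lists of the main comparison. The medial eminence markers had a median of 0.00 over 4 above the filter and −0.09 over all 10 on the array, with the brightest, Lhx6, at −0.68 (9 of 14 listed genes were in other lists), and because the markers of both went both ways and most lay near the low end of the signal range, the tissue explanation stays open without being borne out. A chromosome region carried along with the Pax6 allele was tested because Dlx1 and Dlx2 lie on the chromosome of Pax6. It was put forward for those genes only, and no window was set around Dlx5. Leaving out Pax6, Dlx1 and Dlx2 themselves, 7 of the 49 remaining genes among the 50 nearest to Dlx1 were past 2-fold. That share was 14.3%, the 85.0th percentile of 4579 windows. Around Pax6, which such a region would have to include, 3 of 50 were past 2-fold (6.0%, the 13.4th percentile), which is no excess. The share of 2-fold genes also depends on signal, since 64.6% of them lay in the 3 dimmest of 10 groups. The windows were not matched on signal, so the test leaves this explanation undecided for Dlx1.

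The cell cycle list lay above its random lists. A signal-dependent trend between the arrays does not account for it, since the random lists were matched on signal and share that trend. After loess removal of the trend the list stood at the 100th percentile. Because of the same matching, this adds little to the percentile of the main setting. A larger share of radial glia at the expense of neurons stays open, although the radial glia median was not raised as this explanation predicts. It differed from that of the cell cycle list by −0.47. The criterion set this against the SD of 0.69 among the 19 radial glia genes, which ran from −2.05 for Aldoc to 1.06 for Sox2. That SD describes single genes and not a median. Medians of the matched random lists had smaller SDs, 0.12 for radial glia and 0.08 for the cell cycle. The radial glia median was inside the central 95% of its random lists, at the 23.06th percentile. Toward the side against this explanation, it was at the 4.28th after loess and the 3.22th after quantile scaling. The deep-layer and pan-neuronal medians of −0.43 and −0.25 go with that explanation, the latter only weakly, since it was −0.02 after loess scaling. A genotype effect on proliferation and a difference in developmental stage between the embryos may each account for it as well, and neither was tested.

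Bright probe sets were lower on the mutant array, with a median of −0.27 among the brightest genes. Compression at hybridization or scanning would lower spike-in control probe sets as much as genes of the same signal, most of all the brightest. The 9 spike-in probe sets, from 4 transcripts, had a median deviation of 0.07 (SE 0.07 over probe sets, which are not independent) from the 100 gene probe sets nearest in signal, but 7 lay above their genes and the brightest, CreX, did so by a mean of 0.44, against a technical spread of 0.37. Compression therefore stays open for most of the range and is not borne out at its bright end, which rests on CreX alone. Both CreX probe sets were set against the same gene median of −0.349, so those genes may not match their signal. More degraded RNA in the mutant sample would lower 5′ probe sets more than 3′ ones. The difference was −0.3 for beta-actin and −0.28 for Gapdh, with a mean of −0.29, in the predicted direction. Each was smaller than the technical spread of 0.52 for the difference of a single gene. That spread does not describe a mean over both genes. It comes from all gene pairs at signals above 535, most of them dimmer than these controls. Degradation therefore stays open too.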
